A study of Arabidopsis thaliana with 8 samples.

How the data were processed

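Transcript levels were measured in Arabidopsis protoplasts of 4 groups, SND1XVE control, SND1XVE estradiol, VND7XVE control and VND7XVE estradiol, with 2 arrays per group and 8 in all. Groups and replicate numbers were taken from the sample titles, and the line and treatment from the sample characteristics. Total RNA was labelled with biotin by the 1-cycle Affymetrix kit, per the labels' protocols. The authors' deposited values are array signal intensities on a linear scale, 1 per probe set and array, produced with GCOS per the submitters' processing notes. Its version, summary algorithm and settings are not given in the sources used here, and detection calls were not used here. The 2% trimmed mean of each array was 500.0 or 500.1, so that the deposited intensities had been scaled to a common mean, and array medians differed by at most 1.111 times. They were therefore used as deposited, with no further normalization, although medians were higher on every estradiol array than on any control array. The number of sample columns left unused was 0.

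Probe sets were named only from a table of the platform's annotation, with symbols updated through the NCBI reference genes of Arabidopsis, which were used for names alone. Of 22746 probe sets outside the 64 Affymetrix controls, 13513 named 1 gene, 503 named several and 8730 were not listed in the table used here. Of the 13513, 13436 matched the reference genes and 11933 carry a locus code as their symbol. No genome build is named for the array, so no coordinates are given. A probe set with several or no listed genes is not named. For 88 loci with more than 1 tested probe set, 0 had calls in opposite directions in either estradiol comparison.

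Signals were transformed to log2(signal + 16), which understates the change of genes with low signal, and all folds refer to signals with 16 added. A probe set was tested when it lay above the 40th percentile of the array on at least 2 arrays, which left 14768, of which 8100 named 1 gene. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), with 4 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over the probe sets at a threshold of 0.05. The comparisons were the estradiol effect in each line, the difference between these effects, and the VND7XVE controls against the SND1XVE controls. Fold changes are given with the moderated standard error, and signals with the SD of 2 arrays. A change is called when its adjusted p is under 0.05. The overlap of calls was tested with a one-sided Fisher's exact test. The estradiol comparisons share no control arrays, but they share the estimate of spread for each probe set. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

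Before the data were examined, 19 gene lists with 214 genes in all were fixed for secondary walls, vascular tissue, hormone and stress responses, reference genes and cell types. The annotation named probe sets for 23 of these genes and 21 were tested, so that only 2 of the lists had the minimum of 3 members, and the others enter as single genes. For this reason 23 further lists, of which 21 could be tested, were drawn up from the gene names in the annotation and from background knowledge after the files were seen and before any list was tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 69 tests. The genes named in the text follow a rule fixed beforehand. For each estradiol comparison it takes the 14 largest rises and 8 largest falls among called probe sets that name 1 gene and whose arrays do not overlap, for the other limma comparisons the 5 largest in each direction, and up to 4 members per fixed list; the same was done for 1 added list, genes co-expressed with the secondary wall cellulose synthases, after the files were seen. SND1 and VND7 were to be named in every array and are not analysed here because the table gives their names to no probe set. Other members of the family lists were named after their values were seen.

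The procedure was tested on simulated data for the 14768 probe sets with 200 changed, far fewer than were called in the data. Errors were drawn as independent and normal with spreads from the fitted model, so correlated errors and shifts in scaling were not covered. In the SND1XVE comparison the procedure recovered 78% of 2-fold and 98.5% of 4-fold changes, and in the VND7XVE comparison 70.5% and 97%, with 3% to 5.7% of the calls false. Alternatives were the pseudocount (1 and 64), quantile normalization, median centring, no filter and a filter at the 60th percentile, limma without trend and with robust estimation, the replicate number as a block, only the arrays of 1 line, only probe sets naming 1 gene, a fold minimum, other list tests, and leaving out each array in turn. List tests without the filter on low signal, with 26 lists and 78 tests, were added after the results were seen.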

Results

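Genome-wide transcript levels were measured on 8 Affymetrix arrays hybridised with biotin-labelled RNA from Arabidopsis protoplasts, which are plant cells without their walls. The cells expressed SND1XVE or VND7XVE, estradiol-activated forms of the NAC transcription factors SND1 and VND7, known as switches of secondary wall formation in fibres and in vessels. Controls received cycloheximide, which blocks protein synthesis, and the treated cells received cycloheximide with estradiol. The design asks which genes each factor activates directly, since genes that need newly made proteins should not follow. Each line had 2 control and 2 estradiol arrays. Of 22746 probe sets outside the array controls, 14768 passed the filter on low signal and were tested. Median signals lay between 99.0 and 102.0 intensity units on the control arrays and between 108.3 and 109.9 on the estradiol arrays. Log2 signals of the replicates correlated at 0.982 to 0.988 within the 4 groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. The probe sets of SND1 and VND7, of the secondary wall cellulose synthases and of the wall MYB factors carry no gene name in the tables used here, so these genes were not analysed here.

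In SND1XVE cells, the named genes with the largest rises included IRX15, AT5G66390, AT1G65570 and AT1G70500. IRX15, required for normal xylan in secondary walls, rose by 4.80 ± 0.22 on the log2 scale (SE, n = 2 arrays per group), from a signal of 5.2 ± 1.4 (SD) to 575 ± 27.4. The class III peroxidase gene AT5G66390 (PRX72) rose by 5.36 ± 0.15. The polygalacturonase genes AT1G65570 and AT1G70500, which act on pectin, rose by 5.83 ± 0.31 and 4.96 ± 0.15. On signals with 16 added, the largest named rise was that of AT5G60530, at 6.42 ± 0.13, with signals of 81.2 ± 16.5 in controls and 8276.5 ± 426.8 with estradiol (limma, adjusted p = 9.55e-15).

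Other named genes with large rises were the pectin methylesterase genes AT3G47400 (4.74 ± 0.31) and AT4G02320 (4.01 ± 0.48). AT5G15050, of a glucuronosyltransferase family, rose by 4.73 ± 0.29, and the flavin monooxygenase family gene AT5G07800 by 4.41 ± 0.33. AT4G26880, AT1G35780, AT2G04850, AT5G03510 and AT1G53660 rose by 4.41, 4.15, 4.05, 4.0 and 3.92. Falls were smaller. AT5G22460 fell by 2.71 on the log2 scale, AT1G72920 fell by 2.12, AT5G22530 fell by 1.75 and AT2G44940 fell by 1.60. AT3G20900 fell by 1.90 and AT3G15357 fell by 1.74 (adjusted p = 0.00593 and 0.0288), and both calls were lost without control replicate 2 (adjusted p = 0.0654 and 0.225), that of AT3G15357 also without estradiol replicate 2 (0.264), without the filter (0.103) and without the limma trend (0.122). CLE44, which encodes a precursor of the peptide that keeps vascular cells from becoming xylem, fell by 1.57 on the log2 scale, from 329 ± 29.3 to 104 ± 42.4 (adjusted p = 4.93e-05). The auxin-conjugating enzyme gene GH3.3 fell by 1.42 on the log2 scale (adjusted p = 3.65e-06). TRY, a repressor of trichome formation, fell by 1.76 on the log2 scale (adjusted p = 0.0157), a call lost without control replicate 1 (adjusted p = 0.0505), without control replicate 2 (0.0903) or without estradiol replicate 1 (0.0833).

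Members of the fixed gene lists moved both ways in SND1XVE. Of 4 measured genes of xylan synthesis, IRX15 and GUT2 (the xylan backbone enzyme IRX10, 2.68 ± 0.14) rose, while their relatives IRX15-L and GUT1 had values of -0.42 (adjusted p = 0.0745) and -0.24 (adjusted p = 0.291). Adjusted over the list alone, 2 rose and 1 fell, and as a list they did not pass the threshold (camera, adjusted p = 0.0799, and adjusted p = 0.418 with an estimated correlation). IRX15-L passed the threshold after quantile normalization (adjusted p = 0.0238) and after median centring (0.0222). Of 4 peroxidases, PRX72 rose and PRX52 and AT5G64120 (PRX71) fell by 0.39 and fell by 0.65 on the log2 scale, and AT5G51890 (PRX66) stood at -0.05; adjusted over the list alone, 1 rose and 2 fell. The median of this list was -0.22, its mean was 1.07, and camera gave it the direction down with an adjusted p of 0.994. The call of PRX52 was lost after quantile normalization (0.0604), without the limma trend (0.0796), and without control replicate 1 (0.0742) or estradiol replicate 1 (0.0619). HCT, an enzyme of lignin monomer synthesis, fell by 0.53 on the log2 scale (adjusted p = 0.000837). GSTU25, a glutathione transferase of detoxification, rose by 1.42 ± 0.11. Genes with no call were COB of primary wall cellulose (0.11), LHW of vascular patterning (-0.14), the zinc finger gene AT1G66810 (-0.47), the guard cell gene FMA (-0.56), the auxin-conjugating gene WES1 (-0.15), and the photosynthesis genes RCA (0.04) and LHCB4.1 (0.03). Of the reference genes, AT2G28390 stood at -0.06 and AT4G34270 at -0.31 (adjusted p = 0.125), the latter passing the threshold after quantile normalization (0.0481) and after median centring (0.0309).

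Across the array, 2427 probe sets passed the limma threshold in SND1XVE, of which 1384 rose and 1043 fell. At least 2-fold changes were 531 rises and 100 falls, and 51 rises and 0 falls reached 8-fold, all counted on signals with 16 added, which shrinks falls to low signals such as that of AT5G22460 from 145.8 to 9.0. With a pseudocount of 1, 90 called rises and 2 called falls reached 8-fold, and with 64, 22 and 0. The 2-fold falls numbered 115 with a pseudocount of 1 and 54 with 64. Centring each array on its median gave 1071 rises and 1741 falls, with the median of all probe sets at -0.093 in place of 0.015. Changes of 2-fold were then 455 rises and 170 falls. The count was 1611 without estradiol replicate 1 and 1584 without the limma trend, where falls numbered 676 and 586. Among probe sets with no gene name in the table used here, the 2 largest rises were 5.65 and 5.32. The 3' to 5' signal ratio of actin, a sign of RNA integrity, was 2.80 and 2.87 in SND1XVE controls and 3.301 and 3.206 with estradiol, and that of GAPDH was 1.08 and 0.985 against 1.03 and 0.939.

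In VND7XVE cells, AT1G65570, AT5G66390, AT1G70500 and IRX15 rose as they did in SND1XVE, and AT5G40020 rose the most among named genes. AT5G40020, of the thaumatin family, rose by 7.11 ± 0.31 on the log2 scale (SE, n = 2 arrays per group), from 4.5 in controls to 2833 with estradiol (adjusted p = 5.21e-11). AT1G65570, AT5G66390 (PRX72) and AT1G70500 rose by 6.90 ± 0.31, 6.77 ± 0.15 and 6.57 ± 0.15. AT4G08160, of a family of xylanases, rose by 5.98 ± 0.46. IRX15 rose by 4.87 ± 0.22, and its relative IRX15-L fell by 0.78 on the log2 scale (adjusted p = 0.00177).

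AT3G10590, an MYB-related gene, rose by 6.78 ± 0.30, and AT5G38610, of the pectin methylesterase inhibitor family, by 6.26 ± 0.16. AT5G07800, AT3G47400, AT5G19870, AT5G60530, AT3G52900, AT1G70550 and AT4G18425 rose by 6.52, 6.14, 6.06, 6.03, 6.02, 5.82 and 5.79. AT5G53750 fell by 1.52 on the log2 scale, AT1G52900 fell by 1.35, AT5G24760 fell by 1.32 and AT2G28510 fell by 1.21. AT5G42680 fell by 1.74, AT1G52010 fell by 1.69, AT1G21060 fell by 1.37 and AT5G26270 fell by 1.25 (adjusted p = 0.0223, 0.0283, 0.0178 and 0.0223), and all 4 calls were lost without control replicate 1 (adjusted p = 0.164, 0.113, 0.126 and 0.202) and under at least 2 other settings. Of the xylan list, IRX15 and GUT2 (2.94 ± 0.14) rose, IRX15-L fell and GUT1 stood at -0.23 (adjusted p = 0.347); adjusted over the list alone, 2 rose and 1 fell, and the list did not pass the threshold (camera, adjusted p = 0.0853, and adjusted p = 0.418 with an estimated correlation). Of the 4 peroxidases, PRX72 and AT5G51890 (PRX66, 3.14 ± 0.26) rose, and AT5G64120 and PRX52 fell by 0.65 and fell by 0.41 on the log2 scale; adjusted over the list alone, 2 rose and 2 fell, and the list did not pass the threshold (camera, adjusted p = 0.194). The call of PRX52 was lost without the limma trend (0.0802), without control replicate 1 (0.132) and without estradiol replicate 2 (0.0599). HCT fell by 0.69 on the log2 scale (adjusted p = 7.61e-05) and GSTU25 rose by 1.98 ± 0.11. GH3.3 fell by 0.72 on the log2 scale (adjusted p = 0.00266), a call lost without estradiol replicate 1 (0.0674) and without the limma trend (0.0815). COB (-0.01), LHW (-0.07), AT1G66810 (0.12), FMA (-0.01), WES1 (-0.16), RCA (-0.07), LHCB4.1 (-0.06) and the reference genes AT4G34270 (-0.20) and AT2G28390 (0.24) had no call.

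In VND7XVE 2144 probe sets passed the threshold, with 1204 rises and 940 falls. At least 2-fold changes were 643 rises and 30 falls, and 139 rises and 0 falls reached 8-fold, again with 16 added. With a pseudocount of 1 the 8-fold changes were 190 rises and 2 falls, and the 2-fold falls 48, and with 64 there were 91 rises and 0 falls of 8-fold and 11 falls of 2-fold. Centring gave 1045 rises and 1745 falls, with the median of all probe sets at -0.131 in place of -0.032. Changes of 2-fold were then 592 rises and 76 falls, and 614 and 43 after quantile normalization. The count was 1231 without control replicate 1, 1308 without estradiol replicate 1 and 1326 without the limma trend. Falls moved more than rises, to 372 falls and 859 rises without control replicate 1, 463 and 987 without control replicate 2, 471 and 837 without estradiol replicate 1, and 371 and 955 without the trend. Of probe sets with no gene name in the table used here, the 2 largest rises were 7.91 and 7.20. The actin ratio was 3.72 and 4.16 in VND7XVE controls and 4.64 and 3.98 with estradiol, and that of GAPDH 0.982 and 0.946 against 1.013 and 1.015.

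**Figure D1:**
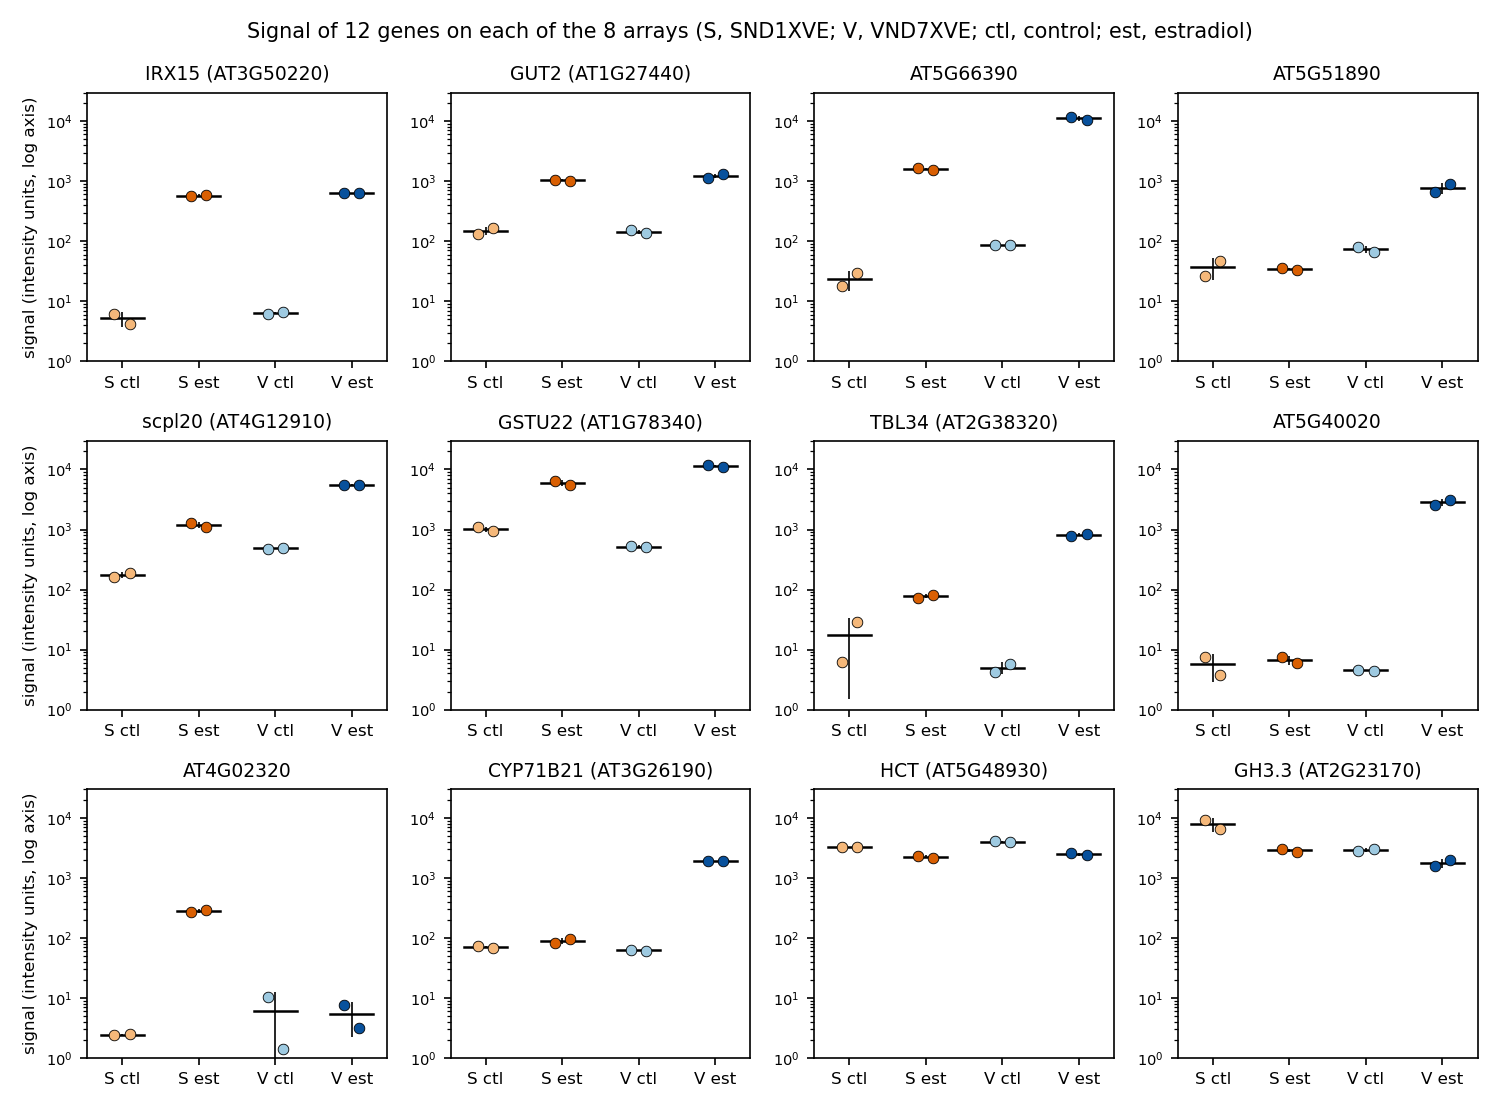
Signal of 12 genes on each of the 8 arrays, in intensity units on a log axis; points are arrays, horizontal bars are means of the 2 arrays of a group and vertical bars are 1 SD. IRX15 and GUT2 were higher with estradiol on all arrays of both lines, the rises of AT5G40020 and CYP71B21 passed the test in VND7XVE, that of AT4G02320 in SND1XVE, and HCT and GH3.3 were lower with estradiol in both lines.

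Gene families chosen after the files were seen, but before any list was tested, were set beside the fixed lists, giving 23 lists and 69 tests with camera at a preset correlation, of which 11, in 6 lists, passed the threshold. With an estimated correlation 0 of the 69 passed, 9 had an unadjusted p under 0.05, and fry called 27. The filter on low signal admits a gene with low signal in controls only where its signal is high on other arrays, so the lists were also tested without it, an alternative chosen after these results were seen. Then 6 of the 11 calls remained. Of 14 named genes known to be co-expressed with the secondary wall cellulose synthases, 7 passed the filter and all of these rose in VND7XVE, with a median of 4.18 (adjusted p = 4.61e-12, and adjusted p = 0.108 with an estimated correlation). AT5G40020, AT1G63520 and AT2G41610 exceeded its level on the VND7XVE estradiol arrays alone, and without the filter 7 of the 14 rose, with a median of 0.99 (adjusted p = 5.77e-06). The others in VND7XVE were AT5G60720 (4.18), AT1G08340 (2.01), TBL34 (5.32), AT1G63520 (2.69) and AT2G41610 (1.37), besides AT5G40020 and AT4G08160. In SND1XVE 3 of the 7 rose, AT5G60720 by 3.78 ± 0.21, AT1G08340 by 2.29 ± 0.28 and TBL34 by 1.56 ± 0.33 (list adjusted p = 0.0126, and adjusted p = 0.302 with an estimated correlation), and the list's call was lost without SND1XVE control replicate 1 (0.0756) and without the filter, where 3 of 14 rose (0.272). Of the 10 serine carboxypeptidase-like genes that passed the filter, 3 rose in SND1XVE and 4 in VND7XVE (list adjusted p = 0.00438 and 0.00663, and adjusted p = 0.273 for both with an estimated correlation), and both list calls were lost without the filter, with 29 genes (0.1 and 0.292). Among them scpl48 rose by 3.46 ± 0.10 and 2.61 ± 0.10, scpl20 by 2.68 ± 0.12 and 3.49 ± 0.12, and scpl29 by 1.83 ± 0.14 and 2.13 ± 0.14. Of 7 tau class glutathione transferases, GSTU22 and GSTU25 rose in VND7XVE, by 4.42 ± 0.11 and 1.98 ± 0.11 (list adjusted p = 0.00974, and adjusted p = 0.281 with an estimated correlation). In SND1XVE 2 of the 7 rose and 1 fell (list adjusted p = 0.232, and adjusted p = 0.46 with an estimated correlation). GSTU22 signals in SND1XVE were 1087.4 and 934.4 in controls and 6531.1 and 5519.5 with estradiol. Of 48 photosynthesis genes, 36 of them plastid-encoded, 4 fell in SND1XVE and 9 fell and 1 rose in VND7XVE. All of these falls were in signals of plastid-encoded genes, whose labelling was not tested. Without the filter 1 gene fell in SND1XVE and 2 fell in VND7XVE. The list was called lower in both lines, with medians of -0.08 and -0.18 (list adjusted p = 0.0329 and 0.00438, and adjusted p = 0.418 and 0.327 with an estimated correlation). Both of these calls were lost after quantile normalization (adjusted p = 0.12 and 0.0872), and the SND1XVE call also without control replicate 2 (0.0714), estradiol replicate 1 (0.136) or the filter (0.0688).

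The lists of genes that responded in the lines overlapped. Rises called in both lines numbered 700, against 113 for independent lists of the same sizes, and shared falls numbered 521 against 66.4 (one-sided Fisher's exact test across probe sets, log10 p = -464 and -393). Both comparisons use the same estimate of spread for a probe set, which favours shared calls, so independent lists are not an exact reference. No group without SND1XVE or VND7XVE received estradiol, so an effect of estradiol itself cannot be told apart from that of the factors. IRX15, GUT2, AT5G60530, AT1G35780 and AT5G15050 were among the shared rises, and the difference between the lines in their effects was 0.06, 0.26, -0.39, 0.22 and 0.18, none of it past the threshold. A further 17 probe sets were called in opposite directions. Across the 14768 probe sets, which are not independent replicates, the effects correlated at Pearson's r = 0.58 and Spearman's rho = 0.48. Shared calls numbered 1221, with 579 rises and 963 falls after centring in place of 700 and 521, and 703 in all without the limma trend, with 192 falls. Shared falls numbered 275 without VND7XVE control replicate 1, 289 without VND7XVE control replicate 2 and 324 without VND7XVE estradiol replicate 1.

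**Figure D2:**
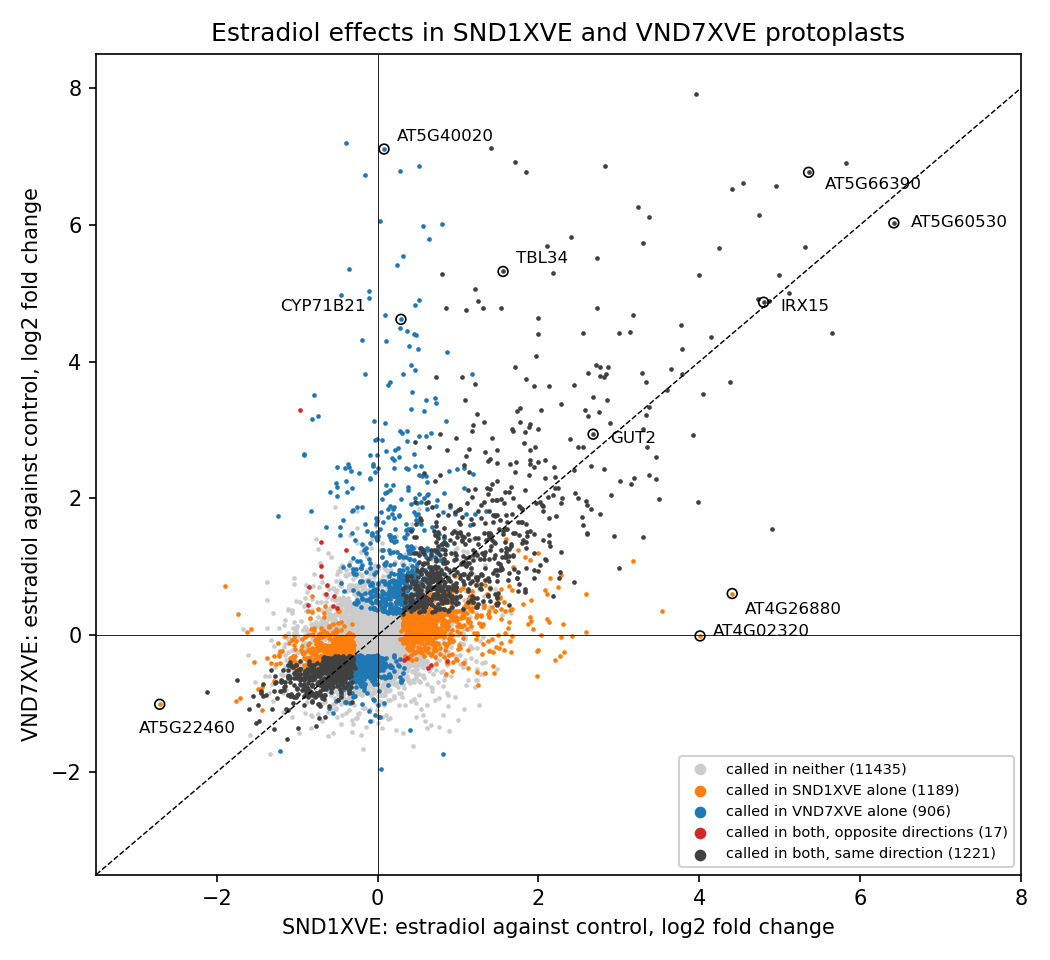
Estradiol effect in SND1XVE (horizontal axis) and VND7XVE (vertical axis), both as log2 fold changes of signal, for the 14768 probe sets tested; colours give the calls and the dashed line marks equal effects. IRX15, GUT2 and AT5G60530 lie near the line, AT5G40020, TBL34 and CYP71B21 above it, and AT4G26880 and AT4G02320 below it.

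Some genes differed between the lines in the size of their response, by the test of the difference itself. AT5G40020 responded more in VND7XVE by 7.04 ± 0.43 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 5.36e-08), with 0.08 in SND1XVE. AT5G19870, AT1G10800, AT2G44260 and AT4G08160 responded more in VND7XVE by 6.03 ± 0.45, 5.72 ± 0.35, 5.43 ± 0.39 and 5.41 ± 0.65. In the other direction AT4G02320, a pectin methylesterase gene, differed by -4.02 ± 0.67 and AT4G26880, of the STIG1 family, by -3.80 ± 0.52, and the effects of both in VND7XVE were not called (-0.01 and 0.61). AT5G18470 and AT2G37070 also responded more in SND1XVE, with differences of -2.56 ± 0.23 and -2.53 ± 0.48.

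The SND1XVE effect of AT4G08160, 0.57 ± 0.46, passed the threshold without SND1XVE control replicate 2 (1.57, adjusted p = 0.00893). The call of AT4G02320 was lost with a pseudocount of 1 (adjusted p = 0.208), and that of AT2G37070 without SND1XVE estradiol replicate 2 (0.0508) or VND7XVE estradiol replicate 2 (0.0522). AT3G56230 differed by -2.56 ± 0.64 (adjusted p = 0.0386), a call lost under 9 of the settings tried. Of the 4 peroxidases, PRX72 and PRX66 responded more in VND7XVE, by 1.40 ± 0.21 and 3.19 ± 0.37, and 0 responded more in SND1XVE (list adjusted p = 0.00438, and adjusted p = 0.273 with an estimated correlation); adjusted over the list alone the counts were also 2 and 0. Of the 4 xylan genes 0 differed in either direction by limma, also adjusted over the list alone, with a median of 0.04, a mean of -0.01 and a camera direction of up (adjusted p = 0.983). Of the genes co-expressed with secondary wall cellulose synthases, 4 of the 7 that passed the filter responded more in VND7XVE (list adjusted p = 8.4e-09, and adjusted p = 0.108 with an estimated correlation), and without the filter 3 of 14 did (0.0003), with TBL34 at 3.75 ± 0.46. Of 9 cytochrome P450 genes tested, which were CYP71B genes and CYP84A4, CYP71B21 was the 1 that differed, at 4.33. The list had a median of 0.22 and a mean of 0.58 (list adjusted p = 0.0126, and adjusted p = 0.361 with an estimated correlation). Its call was lost without SND1XVE control replicate 1, without VND7XVE control replicate 1 and without the filter, with 23 genes (0.339). It therefore rests on CYP71B21 and does not stand for cytochrome P450 genes as a class. Of the tau class glutathione transferases GSTU22 responded more in VND7XVE, by 1.87 (list adjusted p = 0.00438, and adjusted p = 0.273 with an estimated correlation).

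The difference passed the threshold for 452 probe sets, 291 with a higher value in VND7XVE and 161 with a lower one. Of 492 rises called in VND7XVE with no call in SND1XVE, 162 had a called difference, and of 679 rises called in SND1XVE with no call in VND7XVE, 93 did. The count was 232 without VND7XVE estradiol replicate 1, 263 without VND7XVE estradiol replicate 2, 291 without the filter on low signal and 226 without the limma trend. Lower values numbered 72, 102, 95 and 58 under these settings, 97 without SND1XVE estradiol replicate 1, 85 without VND7XVE control replicate 1 and 97 without VND7XVE control replicate 2.

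The control arrays of the lines, both with cycloheximide and without estradiol, differed from each other. The small heat shock protein gene AT1G52560 was higher in VND7XVE controls by 3.45 ± 0.21 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 8.91e-09). AT1G53540 (HSP17.6C) was higher by 2.55 ± 0.10, with signals of 1298 ± 121 in SND1XVE and 7668 ± 254 in VND7XVE controls (SD), and its estradiol effects were -0.03 and -0.12. AT5G48570, of the FK506-binding immunophilins, was higher by 2.38 ± 0.15. AT1G70500 and AT3G27200, which both rose with estradiol, were higher in VND7XVE controls by 3.01 ± 0.15 and 2.95 ± 0.26. Lower in VND7XVE controls were AT2G42060 (-3.17 ± 0.35), AT4G01700, of a chitinase family (-2.97 ± 0.11), the auxin glucosyltransferase gene UGT84B1 (-2.89 ± 0.37), AT5G59680 (-2.89 ± 0.19) and AT2G18210 (-2.86 ± 0.37).

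Of 14768 probe sets, 4067 differed between the control groups, 2026 higher and 2041 lower in VND7XVE. A probe set with no gene name in the table used here had a mean signal of 25743 ± 867 in SND1XVE controls and 23372 ± 2853 with estradiol, against 10.7 and 4.0 in VND7XVE. In mirror image, another unnamed probe set read 26.6 in SND1XVE controls and 109 with estradiol (log2 change 1.65, adjusted p = 4.78e-05), against 23034 ± 1314 and 21820 ± 2783 in VND7XVE. Whether these 2 probe sets measure the introduced genes was not tested, and if they do, their signals are not differences of the plant's own genes. The 3' to 5' signal ratio of actin was 2.80 and 2.87 in SND1XVE controls and 3.72 and 4.16 in VND7XVE controls, while that of GAPDH was 1.08 and 0.985 against 0.982 and 0.946. Line and preparation cannot be told apart here, and the count was 2571 without VND7XVE control replicate 2 and 2601 without VND7XVE control replicate 1.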

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

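Of the tests here, those over shared falls and by the mean of both effects were chosen after the values had been seen. The estradiol effect differed between the lines for 452 probe sets by the interaction test in limma, and 25 of the genes named for the estradiol effects or their difference were among them. In 20 of these the VND7XVE effect was higher. The differences, VND7XVE minus SND1XVE on the log2 scale, were 7.04 for AT5G40020, 6.03 for AT5G19870, 5.72 for AT1G10800, 5.43 for AT2G44260, 5.41 for AT4G08160, 5.21 for AT3G52900, 5.15 for AT4G18425, 4.93 for AT3G10590, 3.75 for TBL34, 3.42 for AT1G70550, 3.19 for AT5G51890, 3.02 for AT5G38610, 2.1 for AT5G07800, 1.61 for AT1G70500, 1.40 for AT5G66390 and 1.28 for AT5G03510. AT3G20900 (2.61), CLE44 (1.66), AT1G72920 (1.29) and AT5G22530 (1.08) had higher values because their SND1XVE effects were falls of -1.90, -1.57, -2.12 and -1.75, against 0.72, 0.09, -0.83 and -0.66 in VND7XVE. The 5 genes with the lower effect in VND7XVE were AT4G02320 (-4.02), AT4G26880 (-3.80), AT3G56230 (-2.56), AT5G18470 (-2.56) and AT2G37070 (-2.53).

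Over all 700 shared rises the VND7XVE effect was higher by a median of 0.05 on the log2 scale and in 378 of them, and over the 597 under 8-fold in both lines by 0.00 (bootstrap interval -0.04 to 0.04). Over the 103 probe sets called higher in both lines and at least 8-fold in either, the VND7XVE effect was higher by a median of 1.22 on the log2 scale and in 82 of them. Split by the mean of both effects instead, the median was 1.22 (0.79 to 1.46) over 70 probe sets of 8-fold or more and 0.01 (-0.02 to 0.05) over the other 630. A lower control level in VND7XVE is argued against. Over the 103 probe sets the controls were higher in VND7XVE by a median of 0.29 and in 69 of them. The bootstrap interval, over probe sets that are not independent, was 0.11 to 0.55. Such a cause would also leave the estradiol arrays alike, but these were higher in VND7XVE by a median of 1.45 (1.04 to 1.95). That value largely repeats the difference in effect. A wider range of all changes on the VND7XVE arrays would also enlarge shared falls, and over 521 of them the VND7XVE effect was smaller by a median difference in size of -0.04 (-0.06 to -0.01). Falls were small, with a median of -0.51 over all called falls in VND7XVE and 0 of 8-fold. They argue against a widening of changes of every size, but cannot show one that acts on large changes alone. Part of the 1.22 may come from the 16 added to each signal, which shrinks a rise more where the control signal is lower. Over the 103 probe sets the lower controls were mostly those of SND1XVE, and the median with another pseudocount was not tested. Besides this and a widening of large changes alone, a difference between SND1 and VND7 in activity or amount stays open. These data may reflect that difference but do not measure it. A difference between the preparations of the lines was not tested and also stays open.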

How the results depend on the processing

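Counts of calls moved by more than 1.5 times under a few settings. Counts are from limma unless said otherwise. Without the trend they were 1584 (SND1XVE), 1326 (VND7XVE), 226 (difference) and 703 (shared), and the cause was not tested. Testing only probe sets that name 1 gene gave 1219 and 1115 in the 2 lines, from fewer probe sets. Requiring 2-fold as well gave 631 and 673, and 2-fold between each estradiol and each control array, with no test, gave 439 and 575. Without the filter on low signal the difference gave 291, with more probe sets in the adjustment. Leaving out 1 array in turn, whose group then has a lone array assumed to vary like the others, gave 1611 to 2289 (SND1XVE), 1231 to 2256 (VND7XVE), 232 to 446 (difference), 2571 to 4100 (controls), 834 to 1082 (shared) and 10 to 14 (list calls, 11 of 69 tests). With an estimated correlation camera made 0 calls, with 9 tests at an unadjusted p under 0.05, and fry, which asks another question, made 27. Without the filter camera made 6 calls in 78 tests, all among the 11, with more members and tests. With the replicate number as a block within each line the counts were 2440, 2160, 424, 2811, 1240 shared and 11 list calls. In that fit the control comparison, with 2811, was of the lines at the level of replicate 1 and not of the group means. With a block across both lines the counts were 2457, 2169, 441, 4075 and 1246 shared. The numbers did not pair the samples, since deviations of arrays with the same number correlated at -0.031 to 0.024. The other alternatives for these counts stayed within 1.5 times. For the named genes, 2068 of 2122 values under an alternative kept their direction and their side of the threshold, 49 lost the call, 5 gained one and 0 changed sign past it. Signals near the background limit the falls of weakly expressed genes, several of which lost their calls when 1 array was left out.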

Other observations

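The list tests and the tallies by genome between the control groups, the tests at higher signal levels and the test on rises of SND1XVE alone were chosen after results had been seen. The low-signal test was first set by control level for both lines together, and was split by line and by mean level after that form had left the answer open. Signals of plastid-encoded genes stood higher in VND7XVE controls than in SND1XVE controls. Whether plastid RNA was labelled equally well in all samples was not tested, so these signals may not follow transcript levels. Of 50 such genes in the photosynthesis and ribosomal protein lists, 44 were higher and 0 lower, with a median of 0.75 on the log2 scale. The ribosomal protein gene rpl33 was higher by 1.80 ± 0.14, psbT, of photosystem II, by 1.63 ± 0.17, and ndhE, of the plastid NADH dehydrogenase-like complex, by 1.60 ± 0.14 (SE, n = 2 arrays per group). Of 48 photosynthesis genes, 39 were higher and 0 lower (camera over 23 lists, adjusted p = 1.34e-18, and adjusted p = 0.0376 with an estimated correlation), with 33 of 36 plastid-encoded and 6 of 12 nuclear members higher. Nuclear members ranged from 0.08 to 1.04, with LHCB4.1 at 1.04 and RCA, not called, at 0.24. The actin 3' to 5' ratio differed in the same comparison, 2.80 and 2.87 in SND1XVE against 3.72 and 4.16 in VND7XVE controls. The 14 ribosomal protein genes tested were all plastid-encoded and are part of the 50 above, and 11 of them were higher (camera, adjusted p = 1.15e-06, and adjusted p = 0.301 with an estimated correlation). Of 10 serine carboxypeptidase-like genes 3 were higher (camera, adjusted p = 0.0464, and adjusted p = 0.301 with an estimated correlation). With estradiol, 5 of the 50 plastid genes fell in SND1XVE and 11 in VND7XVE, where psbM fell by 1.16 on the log2 scale.

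Lower in VND7XVE controls were the WRKY transcription factor gene WRKY53 (-1.94 ± 0.18), PRX52 (-1.85 ± 0.10), AT5G64120 (-1.60 ± 0.11), CYP84A4 (-1.51 ± 0.17), GH3.3 (-1.40 ± 0.15) and GSTU25 (-1.27 ± 0.11). WRKY genes as a list, 3 of 6 lower and 1 higher, did not pass the threshold (adjusted p = 0.0661, and adjusted p = 0.301 with an estimated correlation).

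Genes that responded to estradiol differed between the control groups as well. Of the 139 probe sets that rose at least 8-fold in VND7XVE, 41, or 29.5%, were higher in VND7XVE controls than in SND1XVE controls, and 14, or 10.1%, were lower. In 10000 random lists matched on control level the upper end of the central 95% was 7.9% for higher and 10.1% for lower. Of 51 rises of 8-fold in SND1XVE 39.2% were higher (upper end 11.8%), a share that choosing low SND1XVE controls favours. Of 48 rises of 8-fold in VND7XVE not called higher in SND1XVE, 16.7% were higher (upper end 10.4%). The higher control level of AT1G70500 had been seen before this test was set. Basal activity of VND7XVE without estradiol could give this excess. Choosing rises lowers the chosen controls. For rises chosen in VND7XVE this works against the excess, because the VND7XVE controls enter both comparisons with opposite sign. For rises chosen in SND1XVE it favours the excess, because the SND1XVE controls enter both comparisons with the same sign. A difference between the lines or their preparation that does not come from VND7XVE cannot be told apart from basal activity of VND7XVE, because the design does not separate them. Of the 20 probe sets that rose at least 4-fold in SND1XVE and were not called higher in VND7XVE, 10% were higher in VND7XVE controls. That share lay between the median of 5% and the upper end of 15% of their random lists. It rests on 2 probe sets, and choosing rises in SND1XVE favours the excess, so it could not decide the question.

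Large changes were mostly rises, 84.2% of the called changes of 2-fold or more in SND1XVE and 95.5% in VND7XVE. Scaling of the arrays is argued against, since the share stayed at 72.8% or more after quantile normalization or median centring. Low signals leave little room for falls. In VND7XVE this does not account for the whole excess, because at control signals of 500 or more 85.7% were still rises (exact interval 76.8% to 92.2%). It may account for part, since that share is below the 95.5% at all signals. Where the mean over the 4 arrays of the line reached 500, the share in VND7XVE was 94.5% (89.8% to 97.4%). In SND1XVE low signals may also account for part, since at control signals of 500 or more the share was 55.8% (46.8% to 64.5%), although it was 71.4% (64.1% to 78%) where the mean over the 4 arrays of the line reached 500. Direct activation by the factors remains open as an untested biological explanation.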
